A study of Homo sapiens with 6 samples.

How the data were processed

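tRNA sequencing was done by MSR-seq, a multiplex small-RNA method in which reverse transcription reads through or stops at modified bases, on total RNA of MCF7, an established human breast cancer epithelial cell line. Per the labels' protocols, cells were grown in dialysed serum to deplete queuine (Q_minus) or with 1 µM queuine added (Q_plus), with 3 independent replicates of each, RNA was extracted with TRIzol and libraries were made from 1 µg of total RNA. The labels give the time in queuine as at least 24 h in the growth protocol and at least 48 h in the series design, and the value used is not known here. Samples were assigned to Q_minus or Q_plus from the 0Q and 100Q in their titles, read with the series design. What the 100 in the titles stands for is not stated, and the 1 µM is the dose given in the growth protocol and the series design. What separated the independent replicates is not stated further, so p-values measure the spread between these 6 samples.

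For each library the authors deposited a table of raw counts per reference RNA and a table per position of each reference RNA. The counts in the first table are whole numbers that were not normalised, per the file headers and values. The per-position table holds deposited counts of reads with each base, with a deletion and with an insertion, and their sum as coverage. Its mutation column is a fraction computed by the authors, which equals reads with another base than the reference over the coverage in every line. Its stop column is a score computed by the authors, which equals 1 minus the coverage at a position over that at the next 3' position and is below 0 where coverage rises towards the 5' end. SAMtools and the human build hg38 are named in the submitters' processing notes, without a version or a role. The aligner, trimming, handling of duplicate reads and of reads that match several references are not given in the sources used here. Near-identical tRNA genes (isodecoders) share most of their sequence and reads can be split between them in an unrecorded way, so values of single isodecoders are uncertain and sums per anticodon were tested beside them. A position in the stop test is a net loss of coverage from the next 3' position, set to 0 where coverage rose, since the tables hold coverage and not single read ends. The planned test had named read ends, and the same calculation was used for the read-end profile.

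The references were 260 cytosolic tRNAs, 22 mitochondrial tRNAs and 11 other RNAs, and 277 of the 293 names matched a RefSeq symbol of assembly GRCh38.p14, from which chromosome, start and end were taken. Several identical gene copies can lie behind one reference, and the coordinates given are those of the copy with the same name. Position 34, the first anticodon base, was found from the anticodon in the reference sequence, positions 26, 32 and 37 by their distance from it, position 9 by counting from the 5' end and position 58 as 18 bases before the end of references that include the 3' CCA. Counts per library ranged from 7341978 to 14990543. A count of 3 corresponded to 0.200 to 0.409 CPM, the normalised read count scaled by library size, which is the counting floor alone, and reads without molecular identifiers are not independent molecules.

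Counts per reference RNA and counts summed per anticodon family were tested with the quasi-likelihood test of edgeR 4.0.16 (limma 3.58.1, R 4.3.3), with TMM scaling, a filter at a minimum count of 10 (filterByExpr), the group as the only term and Benjamini-Hochberg adjustment at 0.05. Of 13 lists of tRNAs, the 12 with at least 2 tested members (tRNA-His had 1) were tested with camera at a preset correlation of 0.01 and with an estimated correlation, and with fry. The lists were the cytosolic queuosine (Q) tRNAs together and tRNA-His, -Asn, -Asp and -Tyr alone, mitochondrial Q tRNAs, all mitochondrial tRNAs, A34 tRNAs, mcm5s2U34 tRNAs, long variable arm tRNAs, methionine tRNAs, G34 tRNAs without Q and non-tRNA references. For each position, mutated, deleted or stopped reads were set against the other reads in the same edgeR test with a library term, at sites with a coverage of at least 100 in every library and a pooled share of at least 1%. The same model was run on family sums at positions 32 to 38 of the 8 Q tRNA families, 56 sites per readout with no minimum share, and on 63 sites of G34 families without Q. Shares of reads were compared with exact two-sided permutation tests, whose smallest p for 3 against 3 is 0.1, so that no such test could pass 0.05. Tables, exact tests and plots used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

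The planned comparisons, tests, lists and the rule for named items were fixed before the data were examined. The rule took the 4 cytosolic Q tRNA families, their most abundant isodecoders and the 4 mitochondrial Q tRNAs. It added up to 10 references or families per direction past the threshold without overlap between the groups, or, where fewer than 5 passed, the 5 with the smallest p per direction. For sites it took positions 32 to 38 of the Q tRNAs and up to 10 per direction past the threshold. Alternatives tried were DESeq2 size factors, no scaling, no filter, the Wald test of DESeq2 1.42.0, tRNA counts only, the highest coverage per reference in place of counts, minimum coverages of 20 and 1000, a minimum share of 5%, limma on log2 odds with 0.5 added to each count, the most covered isodecoder of a family alone, other region limits, replicate number as a block, and leaving out each library in turn. Added after the data were seen were removal of each library's background per base, the ratio to G34 of tRNAs without Q, modification classes without the Q tRNAs, tRNA counts only for families and lists, lists without scaling, and library shares with rRNA apart. The loop test of G34 families without Q and the read ends of families without Q were also not in the plan.

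The tests were tried on simulated counts with known changes. Noise was drawn independently for each reference or site, without shifts shared by a whole library, so recovery in the real libraries can be lower. For abundance of 280 references, 65.5% of 2-fold and 100% of 4-fold changes were recovered, with 1 false call, and for 81 families 80% and 100%, with 0 false calls. For an odds ratio of 2 or 4, the recovered shares were 23% and 56% of changed sites for mutation, 15% and 42% for deletion and 1% and 29% for stops, with 7, 1 and 3 false calls. Among the 56 loop sites, with 7 changed at each size, 14.3% were recovered at either odds ratio for mutation, 0% and 14.3% for deletion and 0% for stops, with 0 false calls, so a loop site that did not pass can still differ by that much.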

Results

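Queuosine (Q) is a modified guanosine that replaces G34, the first anticodon base, in tRNA-His, tRNA-Asn, tRNA-Asp and tRNA-Tyr of the cytosol and of mitochondria. It is made from queuine, a base that human cells take up from diet and gut bacteria, so cells in dialysed serum lose it. The series title concerns a tRNA-His fragment that depends on Q, and the libraries compare MCF7 breast cancer cells without queuine (Q_minus, n = 3) and with 1 µM queuine (Q_plus, n = 3). Total counts were 8029435, 11846919 and 7341978 in Q_minus replicates 1 to 3 and 14990543, 9613901 and 10106156 in Q_plus replicates 1 to 3. Every pair of replicates differed by far more than sampling noise, with a chi-square per degree of freedom of at least 487.

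Cytosolic tRNA made up 66.8% ± 2.89 (SD, n = 3) of counts in Q_minus and 66.7% ± 13.1 in Q_plus, and mitochondrial tRNA 1.90% ± 0.215 and 2.02% ± 0.466. The 4 cytosolic Q tRNA families held 12.9% ± 0.307 and 12.9% ± 3.31. Other references, mostly 5S and 5.8S rRNA, held 31.3% ± 2.74 and 31.3% ± 13.4. Exact two-sided permutation tests gave p from 0.7 to 1 for these shares, where 0.1 is the smallest possible. In Q_plus replicate 1, 5S and 5.8S rRNA held 43.2% of counts and cytosolic tRNA 52.3%. Without that library cytosolic tRNA was 7.14 percentage points higher in Q_plus than in Q_minus, and the difference was -0.0550 percentage points with all libraries.

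The first comparison asked whether tRNA levels differ with queuine. No anticodon family passed the test. Cytosolic tRNA-His was at 4775 ± 1059 CPM (SD, n = 3) in Q_minus and 3806 ± 1418 in Q_plus, a log2 fold change of -0.33 (SE 0.26). tRNA-Asn was at 19817 ± 2300 and 15678 ± 2144 CPM, with every Q_plus library below every Q_minus library (log2 fold change -0.34, SE 0.17, edgeR adjusted p = 0.794). tRNA-Asp, the most abundant of the 4, was at 72856 ± 4392 and 79174 ± 12046 CPM, and tRNA-Tyr at 28970 ± 3881 and 30212 ± 2095, with log2 fold changes of 0.12 (SE 0.20) and 0.06 (SE 0.17). Among the mitochondrial Q tRNAs the log2 fold change was -0.21 for mt-tRNA-His (310 ± 46.3 and 267 ± 37.9 CPM), 0.56 for mt-tRNA-Asn (231 ± 62.4 and 342 ± 65.6 CPM), 0.25 for mt-tRNA-Tyr (593 ± 135 and 704 ± 193 CPM) and 0.01 for mt-tRNA-Asp (43.4 ± 8.70 and 43.7 ± 7.38 CPM), the last turning to -0.01 without scaling, -0.06 without Q_minus replicate 2 and -0.04 without Q_plus replicate 2. That of tRNA-Tyr turned to -0.03 without Q_minus replicate 3. For tRNA-His it was -0.68 without Q_plus replicate 1, -0.09 without Q_plus replicate 2, -0.10 without Q_plus replicate 3 and -0.18 without Q_minus replicate 1, and for tRNA-Asn it was -0.16 without Q_plus replicate 2.

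Outside the Q tRNAs, initiator tRNA-Met (iMet-CAT), which reads the start codon, had the smallest p of the families. It was at 8231 ± 3186 CPM in Q_minus and 4373 ± 1079 in Q_plus (log2 fold change -0.91, SE 0.28, edgeR adjusted p = 0.55). In edgeR it passed without Q_minus replicate 1 (adjusted p = 0.0484) or without Q_plus replicate 1 (adjusted p = 0.0281), the only leave-outs with a family past the threshold, and over all alternatives its adjusted p ranged from 0.000219 to 0.996. Mitochondrial tRNA-Met had a log2 fold change of -1.11 (SE 0.49), with 513 ± 451 CPM in Q_minus and 238 ± 57.6 in Q_plus, and Q_minus replicate 3 alone was at 1034 CPM. tRNA-Gly-CCC and tRNA-Gln-CTG had values of -0.41 and -0.39. On the higher side stood mt-tRNA-Ser-TGA (0.51, SE 0.23), the spliceosomal RNAs RNU2-1 (0.72) and RNU1-1 (0.46), and tRNA-Pro-CGG (0.28). In Q_plus replicate 1 RNU2-1 was at 14188 CPM and RNU1-1 at 10422, against 3760.0 to 5845 and 3948 to 5649 CPM in the other 5 libraries, and without that library their log2 fold changes were 0.07 and 0.01. In the edgeR quasi-likelihood test, 0 of 81 families passed after Benjamini-Hochberg adjustment and 3 had an unadjusted p under 0.05, against 0 and 5 with DESeq2. The groups did not overlap for 9 families (11.1%), where chance gives 10%.

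**Figure D1:**
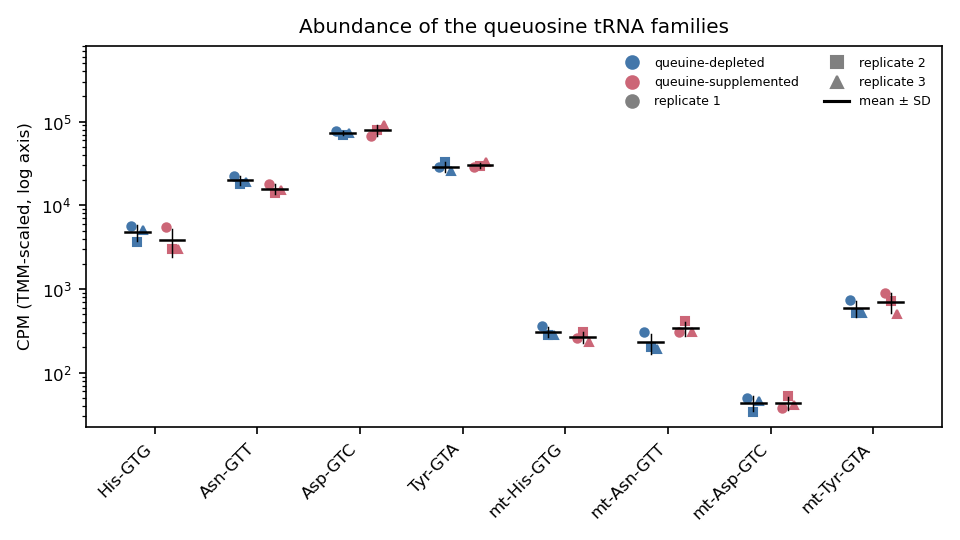
Abundance of the 8 Q tRNA families in CPM (log axis) in each of the 6 libraries, with points for libraries, horizontal bars for group means and vertical lines for the SD (n = 3). tRNA-Asn was lower in every Q_plus library (means of 19817 and 15678 CPM), and the groups overlapped in the other families.

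Single isodecoders of tRNA-Asn at low abundance had the smallest p of all references, with values in opposite directions. tRNA-Asn-GTT-27-1 (chromosome 1, 121048432 to 121048505) was at 3.57 ± 0.477 CPM in Q_minus and 11.3 ± 2.98 in Q_plus, a log2 fold change of 1.65 (SE 0.35). tRNA-Asn-GTT-9-1 (chromosome 1, 145475381 to 145475454) was at 7.39 ± 1.07 and 1.55 ± 1.02 CPM, a log2 fold change of -2.25 (SE 0.47). Each had an adjusted p of 0.0807 with edgeR and 0.000874 with DESeq2, and these were the only calls of DESeq2. Over all alternatives the highest adjusted p of either was 0.526, and the lowest was 0.000874 for tRNA-Asn-GTT-27-1 and 0.000169 for tRNA-Asn-GTT-9-1. Near-identical copies can exchange reads, so these values are uncertain. tRNA-Asn-GTT-8-1 had a log2 fold change of 0.95 (12.7 ± 3.65 and 24.5 ± 6.29 CPM) and tRNA-Asn-GTT-5-1 one of -0.60 (37.3 ± 5.14 and 24.5 ± 2.66 CPM). The most abundant isodecoders were closer to 0, with -0.22 (SE 0.20) for tRNA-Asn-GTT-3-1 (chromosome 1, 144419267 to 144419340), -0.22 (SE 0.29) for tRNA-His-GTG-1-1 (chromosome 1, 146038044 to 146038115), 0.20 (SE 0.19) for tRNA-Asp-GTC-2-1 (chromosome 1, 161440825 to 161440896) and 0.18 (SE 0.19) for tRNA-Tyr-GTA-5-1 (chromosome 8, 66113367 to 66113459, an intron-containing gene).

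The other references with the smallest p were mt-tRNA-Asn (0.65, SE 0.24), tRNA-Cys-GCA-21-1 (1.05, SE 0.44) and mt-tRNA-Ser-TGA (0.61, SE 0.26) on the higher side, and tRNA-iMet-CAT-1-1 (-0.84, SE 0.28), tRNA-Lys-CTT-3-1 (-1.18, SE 0.45) and tRNA-Val-TAC-4-1 (-0.82, SE 0.31) on the lower side, all with an edgeR adjusted p of 0.655. Of 282 references, 0 passed the edgeR test after Benjamini-Hochberg adjustment and 13 had an unadjusted p under 0.05, against 2 and 17 with DESeq2. The groups did not overlap for 28 references (9.93%), where chance gives 10%. Without Q_plus replicate 1 the edgeR test called 5, namely tRNA-Asn-GTT-27-1, tRNA-Asn-GTT-9-1, tRNA-Asp-GTC-3-1, tRNA-Lys-CTT-3-1 and mt-tRNA-Met. Without scaling it called 1, tRNA-Asn-GTT-9-1, and the median log2 fold change of all references was -0.12 in place of -0.01.

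As groups, the cytosolic Q tRNAs (26 members, 10 with a positive log2 fold change) had a median of -0.11, tRNA-Asn (14, 4 positive) -0.28, tRNA-Asp (3, all positive) 0.20 and tRNA-Tyr (8, 3 positive) -0.08. Mitochondrial Q tRNAs (4, 3 positive) had a median of 0.22 and all mitochondrial tRNAs (22, 12 positive) 0.10. A34 tRNAs, whose adenosine is edited to inosine, had a median of -0.03 (51, 23 positive), mcm5s2U34 tRNAs 0.02 (25, 15 positive), long variable arm tRNAs -0.01 (38, 18 positive), methionine tRNAs -0.09 (9, 1 positive), G34 tRNAs without Q 0.03 (35, 20 positive) and non-tRNA references 0.34 (11, 8 positive). Camera, which compares a list with all other references, called 0 of the 12 lists after Benjamini-Hochberg adjustment, and 1, tRNA-Asn, had an unadjusted p under 0.05 (p = 0.0487 in camera, adjusted p = 0.363, p = 0.429 with an estimated correlation). For movement of a list's members on balance in 1 direction, fry gave adjusted p of at least 0.850, with 0 lists at an unadjusted p under 0.05. Without scaling, an alternative added after the data were seen, fry called tRNA-Asn in the negative direction (adjusted p = 0.0352, up to 0.999 over all alternatives). Its mixed test, which asks whether members change in either direction, called the cytosolic Q tRNAs (adjusted p = 0.00266) and tRNA-Asn (adjusted p = 0.00222), and in each list 2 members passed when adjusted over the list alone, against 0 over all references and 0 in each of the other 10 lists. The 2 members were the same in both lists, tRNA-Asn-GTT-27-1 and tRNA-Asn-GTT-9-1 at low abundance. tRNA-Asn supplies 14 of the 26 cytosolic Q tRNAs, so the calls are not independent. Both calls were lost without Q_minus replicate 1, where these mixed adjusted p of fry were 0.109 and 0.0926, and with the replicate number as a block, where each was 0.1005 (from 0.000394 over all alternatives). Without Q_plus replicate 1 camera called tRNA-Asn as lower (adjusted p = 0.00147), tRNA-Asp as higher (0.0317) and the non-tRNA references as lower (0.0317, median -0.37). Without Q_plus replicate 3 it called the non-tRNA references in the opposite direction, as higher (0.0179, median 0.54). None of these camera calls held with an estimated correlation, where their adjusted p ranged from 0.493 to 0.871, and over all alternatives the highest camera adjusted p of these lists was 0.886. For tRNA-Tyr the mean of -0.01 and the median were negative and camera's direction positive, and for mcm5s2U34 tRNAs the mean of -0.01 was negative and the median and camera's direction positive.

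The second comparison asked how reads differ at the anticodon loop, positions 32 to 38, where Q sits at position 34. Mutation fell at 2 sites near that base in Q_plus. At A36, the last anticodon base of tRNA-Tyr, mutated reads were 0.219% ± 0.0638 (SD, n = 3) in Q_minus and 0.0325% ± 0.00353 in Q_plus, a log2 odds ratio of -2.72 (SE 0.29, edgeR adjusted p = 9.51e-05). At C32 of tRNA-Asn they were 0.312% ± 0.0247 and 0.0983% ± 0.0199, a log2 odds ratio of -1.68 (SE 0.28, edgeR adjusted p = 0.00227). Coverage was at least 194330 reads per library at the tRNA-Tyr site and at least 140406 at the tRNA-Asn site.

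With positions numbered so that 34 is the first anticodon base and the reference base written first, A36G made up 95.4% of the mutated reads at the tRNA-Tyr site in Q_minus, at 0.209% ± 0.0659 of reads against 0.0268% ± 0.00362 in Q_plus. At the tRNA-Asn site C32T was at 0.210% ± 0.0377 of reads in Q_minus and 0.0556% ± 0.00955 in Q_plus and C32A at 0.0605% ± 0.0170 and 0.0284% ± 0.00684, each without overlap (exact two-sided permutation p = 0.1, the smallest possible). All 9 isodecoders of these families that were tested alone, with at least 3334 reads per library, were lower in Q_plus without overlap, with log2 ratios from -1.58 to -1.70 for the 3 of tRNA-Asn and from -2.04 to -2.99 for the 6 of tRNA-Tyr. These isodecoders are parts of the family sums and can share reads, so they are not independent of the sums or of each other. Of the 56 loop sites, 2 passed and 11 had an unadjusted p under 0.05. Both sites passed in every leave-out, but the number of calls was 4 without Q_minus replicate 1, 8 without Q_plus replicate 1 and 8 without Q_plus replicate 2. In G34 families that carry no Q, 1 of 63 loop sites passed, T33 of tRNA-Gly-GCC, at 0.146% ± 0.0227 and 0.0822% ± 0.00888 (log2 odds ratio -0.82, edgeR adjusted p = 0.0412).

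**Figure D2:**
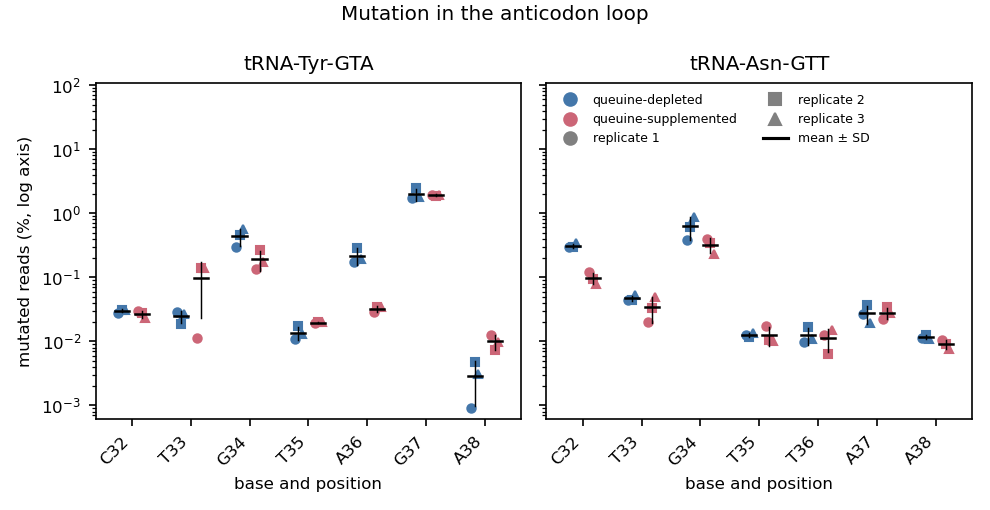
Mutated reads in percent (log axis) at positions 32 to 38 of tRNA-Tyr and tRNA-Asn in each of the 6 libraries, with points for libraries, horizontal bars for group means and vertical lines for the SD (n = 3). All Q_plus libraries lie below all Q_minus libraries at C32 of tRNA-Asn and A36 of tRNA-Tyr, with means of 0.312% and 0.0983% for tRNA-Asn and 0.219% and 0.0325% for tRNA-Tyr.

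At G34 itself no mutation difference passed the edgeR test. tRNA-Tyr was at 0.439% ± 0.130 in Q_minus and 0.191% ± 0.0659 in Q_plus (adjusted p = 0.0618 in edgeR), tRNA-Asp at 4.73% ± 1.39 and 2.27% ± 1.03, tRNA-Asn at 0.627% ± 0.244 and 0.324% ± 0.0860, and tRNA-His at 0.493% ± 0.1201 and 0.326% ± 0.213. The mean log2 level at G34 of cytosolic Q families differed by -1.02 (exact permutation p = 0.1), that of cytosolic G34 families without Q by -0.89 (p = 0.3), and the difference between them was -0.13 (p = 0.8), all two-sided. The value of G34 families without Q was -0.46 without Q_plus replicate 1, and the difference between the 2 kinds was -0.30 without that library, -0.03 without Q_minus replicate 1 and 0.08 without Q_plus replicate 3.

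Deletions at G34 were lower in Q_plus without overlap in 6 of the 8 Q families, where chance gives 10% in either direction, and none passed the edgeR test. tRNA-Asp was at 6.24% ± 1.65 of reads in Q_minus and 1.495% ± 0.819 in Q_plus (log2 odds ratio -2.29, SE 0.75), tRNA-His at 3.98% ± 1.203 and 1.32% ± 0.0808 (-1.59, SE 0.49) and tRNA-Tyr at 0.407% ± 0.152 and 0.122% ± 0.0513 (-1.78, SE 0.65), each with an adjusted p of 0.140 in edgeR. tRNA-Asn was at 1.58% ± 0.548 and 0.889% ± 0.611, with overlap. In mitochondria the shares were 18.6% ± 1.98 and 8.41% ± 3.69 for mt-tRNA-His, 13.1% ± 2.61 and 6.44% ± 2.32 for mt-tRNA-Asn, 8.57% ± 2.54 and 3.25% ± 1.07 for mt-tRNA-Tyr, and 5.09% ± 3.54 and 3.28% ± 2.83, with overlap, for mt-tRNA-Asp, which had at least 296 reads per library. T35 of mt-tRNA-Tyr came closest to the threshold, at 2.04% ± 0.597 and 0.219% ± 0.137 (log2 odds ratio -3.23, SE 0.67, edgeR adjusted p = 0.0534). Of the 56 loop sites, 0 passed the edgeR test for deletion and 13 had an unadjusted p under 0.05, and 3 passed with each library's background removed, an alternative added after the data were seen.

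G34 of tRNAs that carry no Q was also lower in Q_plus for deletion, with log2 ratios of -1.40 for tRNA-Cys, -0.98 for tRNA-Gly-GCC, -1.25 for tRNA-Ser-GCT and -2.29 for mt-tRNA-Phe, each without overlap (4 of 9 families). The mean log2 deletion level of cytosolic Q families differed by -1.68 (exact permutation p = 0.1) and by -0.60 (p = 0.2) relative to cytosolic G34 families without Q. For mitochondrial Q families the values were -1.20 (p = 0.1) and 0.14 (p = 0.8), all two-sided. When Q_plus replicate 1 was left out they were -0.67 and -0.14, and the second was 0.42 without Q_plus replicate 3, 0.26 without Q_minus replicate 1 and -0.0024 without Q_minus replicate 3. Without Q_plus replicate 1 the edgeR test called 7 deletion sites, among them G34 of tRNA-Asp (adjusted p = 0.0186) and of tRNA-His (adjusted p = 0.0328), whose highest adjusted p over all alternatives was 0.431, and without Q_plus replicate 2 it called 1, T35 of mt-tRNA-Tyr.

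**Figure D3:**
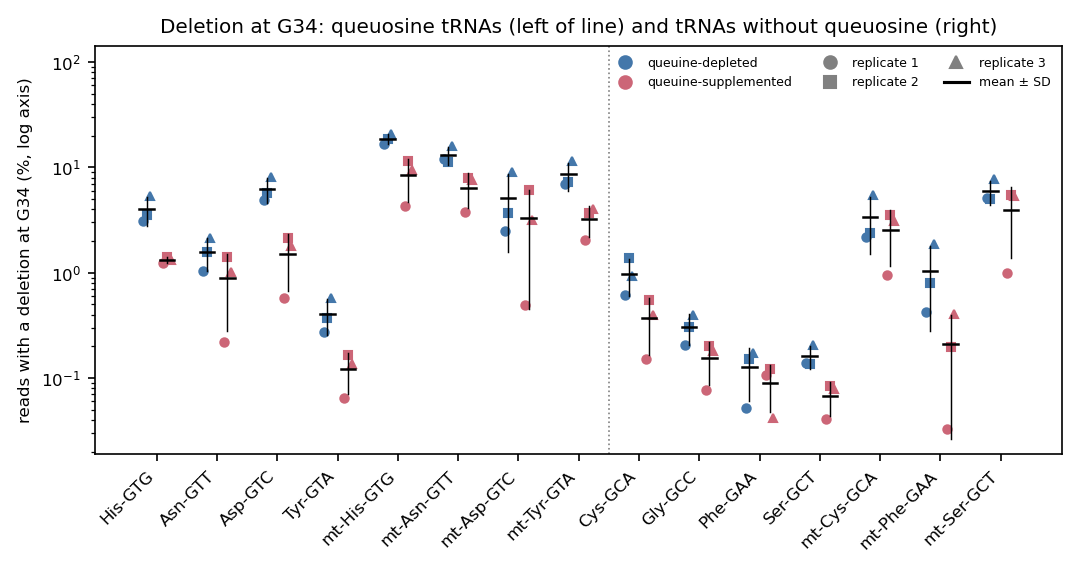
Deleted reads in percent (log axis) at G34 of the Q tRNA families and of G34 families without Q, in each of the 6 libraries, with points for libraries, horizontal bars for group means and vertical lines for the SD (n = 3). Mean shares were lower in Q_plus in both kinds of tRNA, such as 6.24% and 1.495% for tRNA-Asp and 0.971% and 0.367% for tRNA-Cys, which has no Q.

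Loss of coverage at the loop, read as reverse transcription stops or fragment ends, was 0.685% ± 0.277 in Q_minus and 0.119% ± 0.0484 in Q_plus at T33 of tRNA-Asn (edgeR adjusted p = 0.299), the smallest p among the loop sites. At G34 it was 1.00% ± 0.335 and 0.450% ± 0.190 for tRNA-Tyr and 0.405% ± 0.167 and 0.309% ± 0.276 for tRNA-His. Of the 56 loop sites, 0 passed the edgeR test for stops and 6 had an unadjusted p under 0.05, and without Q_minus replicate 1 it called 1, C36 of tRNA-Asp.

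The third comparison covered all sites with the minimum coverage and a pooled share of at least 1%. As family sums, A36 of tRNA-Tyr and C32 of tRNA-Asn lay below that share for mutation. For mutation 0 of 2126 sites passed the edgeR test after Benjamini-Hochberg adjustment (86 at an unadjusted p under 0.05, 0 and 97 with limma, and 1 past the threshold with the background removed), for deletion 0 of 2041 (94, and 0 and 104 with limma) and for stops 0 of 3150 (180, and 0 and 182 with limma). The median log2 odds ratios over these sites were -0.28, -0.45 and -0.40, and at a minimum share of 5% they were 0.02, -0.20 and -0.28, so that the sign turned for mutation. Mutation at guanosines outside the Q tRNAs, relative to the mean of the libraries, was -1.02 (log2) in Q_plus replicate 1 and between -0.02 and 0.70 in the other 5 libraries. At the other bases it was 0.13 for A, 0.05 for C and -0.08 for T in Q_plus replicate 1. Without that library the medians over all sites were -0.11, -0.16 and -0.20, and without Q_minus replicate 3 they were -0.18, -0.28 and -0.22. The smallest p for deletion were at G37 of tRNA-Tyr isodecoders, next to A36. Deleted reads were 1.85% in Q_minus and 0.539% in Q_plus for tRNA-Tyr-GTA-2-1, and 1.92% and 0.585% for tRNA-Tyr-GTA-5-1. For tRNA-Tyr-GTA-6-1 they were 4.49% and 1.33%. Each was without overlap, with an edgeR adjusted p of 0.293, and of 0.542 with the background removed. These isodecoders can share reads.

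The mean mutation share was 29.96% ± 0.506 in Q_minus and 30.7% ± 0.529 in Q_plus at position 9 (methylated purines), 25.2% ± 0.117 and 24.8% ± 0.0676 at G26 (dimethylguanosine), 76.9% ± 1.02 and 78.9% ± 1.29 at C32 (methylcytidine), 93.9% ± 0.594 and 94.9% ± 0.452 at A34 (inosine), 39.1% ± 0.627 and 39.5% ± 0.338 at position 37, and 45.8% ± 2.11 and 47.9% ± 1.45 at A58 (methyladenosine). The groups did not overlap at G26, lower in Q_plus, and at A34, higher in Q_plus, 2 of 6 classes where chance gives 10%. Both had an exact two-sided permutation p of 0.1, the smallest possible, and a Benjamini-Hochberg adjusted p of 0.3.

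The fourth comparison concerned where the 5' ends of reads of Q tRNAs lie, a measure of full-length reading against stops or fragments. For tRNA-Asn 16.04% ± 2.005 of ends lay at positions 1 to 5 in Q_minus and 22.9% ± 1.204 in Q_plus, and 64.8% ± 0.493 and 58.9% ± 2.43 at positions 27 to 43, the anticodon arm. For tRNA-His the shares were 57.8% ± 5.21 and 63.3% ± 10.96 at positions 1 to 5, and 4.08% ± 0.496 and 2.56% ± 1.07 in the anticodon arm. Without Q_plus replicate 1 the tRNA-His differences went from 5.56 to -0.744 percentage points at positions 1 to 5 and from -1.52 to -0.910 in the anticodon arm, and without Q_minus replicate 3 the first was 2.62. For tRNA-Tyr 95.8% ± 0.147 and 95.9% ± 0.0691 of ends lay in the anticodon arm. tRNA-Asp had 40.4% ± 9.91 and 46.7% ± 13.3 of ends at positions 1 to 5, and mt-tRNA-Asn 45.3% ± 11.5 and 63.3% ± 11.1. The tRNA-Asp difference went from 6.34 to -1.21 percentage points without Q_plus replicate 1, and was 0.659 without Q_minus replicate 3. The share at positions 1 to 5 was also higher on average in Q_plus in 58 of 61 families without Q, and was 0 in both groups in the other 3. In these families the median difference was 6.06 percentage points and the highest 15.3, for mt-tRNA-Val, against 6.85 for tRNA-Asn and 17.9 for mt-tRNA-Asn. When Q_plus replicate 1 was left out the median was 2.93 and the values of mt-tRNA-Val, tRNA-Asn and mt-tRNA-Asn were 13.6, 7.39 and 11.8, with 2 of the families without Q lower in Q_plus. Without Q_minus replicate 3 they were 3.08, 9.74, 5.69 and 11.4, also with 2 lower, and another family without Q had the highest value, 10.2. The groups did not overlap for 9 of the 61 (14.8%, where chance gives 10%), among them tRNA-Leu-AAG and tRNA-Pro-AGG. Among 32 exact two-sided permutation tests the smallest p was 0.1, as low as 3 against 3 libraries allow, and the smallest Benjamini-Hochberg adjusted p was 0.533.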

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

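The alternatives of background removal, tRNA counts only for families and lists, lists without scaling, the ratio to tRNAs without Q, modification classes without the Q tRNAs and rRNA apart were chosen after seeing the data, and all other alternatives before. For counts of calls, 108 of the recomputed values were within 1.5 times the reported count and 18 were not, and for named values 692 kept their direction and side of the threshold, 15 kept their direction and passed it, and 46 changed sign. The cause was not tested for any of them. Both sets of numbers include the exact permutation tests, which could not pass at any setting and so could not change side. Of the other reported counts only that for loop mutation had any call, and a count without calls is matched only by another without calls. A36 of tRNA-Tyr and C32 of tRNA-Asn passed under every alternative and every leave-out.

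For abundance of references, where 0 passed, 1 passed without scaling, 2 with DESeq2 and 0 to 5 when 1 library was left out. For anticodon families leave-outs gave 0 to 1. For the lists leave-outs gave 0 to 3 camera calls. With the background of each library removed, 1 site passed for mutation over all sites, and 3 loop sites passed for deletion (G34 of tRNA-Asp, T33 and T35 of mt-tRNA-Tyr). Leave-outs gave 2 to 8 loop sites for mutation, 0 to 7 for deletion and 0 to 1 for stops.

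The replicate numbers gave no uniform sign of pairing, and the samples were not treated as pairs. Deviations of the libraries numbered 2 correlated at -0.43 over references, -0.33 over families and -0.29 over mutation sites. For the libraries numbered 1 these values were 0.41, 0.33 and 0.16, and for those numbered 3 they were 0.18, -0.13 and 0.18. Not every library correlated best with its own number. With the replicate number as a block, 1 family passed (iMet-CAT, edgeR adjusted p = 0.000219, the lowest of a range up to 0.996 over all alternatives), 6 loop sites passed for mutation, 1 for deletion and 0 for stops, and 0 references, camera lists, lists in fry's mixed test and sites over all sites.

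Most changes of sign were in values near 0. The mean deletion level at G34 of mitochondrial Q tRNAs went from -1.20 to 0.14 as a ratio to tRNAs without Q. The log2 fold change of mt-tRNA-Asp was -0.0057 without scaling and -0.059 to 0.13 over leave-outs, and that of tRNA-Tyr -0.026 to 0.26. With no filter, the mean of the list was 0.084 for cytosolic Q tRNAs, 0.0155 for tRNA-Asn, 0.20 for tRNA-Tyr, 0.0099 for mcm5s2U34 tRNAs and -0.023 for G34 tRNAs without Q. With DESeq2 size factors it was 0.0055 for tRNA-Tyr and 0.0084 for mcm5s2U34 tRNAs, and without scaling -0.048 for all mitochondrial tRNAs and -0.12 for G34 tRNAs without Q. Over leave-outs the means ranged from -0.16 to 0.080 for cytosolic Q tRNAs, -0.38 to 0.058 for tRNA-Asn, -0.029 to 0.26 for tRNA-Tyr, -0.086 to 0.17 for all mitochondrial tRNAs, -0.052 to 0.030 for mcm5s2U34 tRNAs, -0.11 to 0.14 for G34 tRNAs without Q and -0.29 to 0.52 for non-tRNA references. The difference in library share, in percentage points, ranged over leave-outs from -5.69 to 7.14 for cytosolic tRNA, -0.113 to 0.352 for mitochondrial tRNA, -1.36 to 1.89 for cytosolic Q tRNA and -7.50 to 5.55 for other references, and was -0.0934 for Q tRNA as a share of tRNA counts. The read-weighted mutation share at position 37 differed by -0.639 percentage points, against 0.408 as a mean over sites. Low-coverage references such as mt-tRNA-Asp, with at least 296 reads per library at G34, limit what the site tests can show.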

Other observations

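Insertions at G34 and read 3' ends belong to no planned comparison, and their tests and those of the 3 patterns below were chosen after the results were seen. Insertions at G34 fell in the most abundant tRNA-Asn isodecoders. At tRNA-Asn-GTT-2-1 they were 0.334% ± 0.0771 (SD, n = 3) of reads in Q_minus and 0.0359% ± 0.0131 in Q_plus (log2 odds ratio -3.23, SE 0.47), and at tRNA-Asn-GTT-3-1 0.386% ± 0.101 and 0.0325% ± 0.0145 (log2 odds ratio -3.61, SE 0.49), each with an edgeR adjusted p of 0.0397. These were the 2 of 605 tested sites that passed for insertion, and 19 had an unadjusted p under 0.05. For insertion the minimum pooled share was 0.1% in place of 1%, and no leave-out, background removal or other alternative was run. Insertions over all coverage ranged from 0.0043% in Q_plus replicate 1 to 0.0134% in Q_minus replicate 3. The isodecoders share sequence, so they are not independent.

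The 3' ends of tRNA-His reads, inferred from gains of coverage, lay at positions 27 to 50 in 6.32% ± 4.86 of reads in Q_minus and 9.10% ± 2.41 in Q_plus (exact two-sided permutation p = 0.5). The Q_minus mean leaned on replicate 3, with 2.37%, 4.84% and 11.7% in Q_minus replicates 1 to 3. Q_plus replicates 1 to 3 were at 11.7%, 8.55% and 7.01%. As a mean over the 6 libraries the share of tRNA-His was the highest of 68 families, ahead of mt-tRNA-Ser-GCT at 5.47%, but another family was higher in 4 of the 6 libraries. In the group means, though not in Q_minus replicate 2, most of it lay at A45, at 1.27%, 2.10% and 8.97% in Q_minus replicates 1 to 3 and 8.71%, 5.25% and 3.63% in Q_plus replicates 1 to 3 (exact permutation p = 0.6). Mutation at the adenosine at position 43 of the mt-tRNA-Leu-TAG reference was 2.76% ± 0.535 and 0.310% ± 0.0920 (edgeR adjusted p = 0.0961, and 0.0222 with the background removed), a site named after its values were seen.

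Mutation at A36 of tRNA-Tyr and C32 of tRNA-Asn was lower in Q_plus. A library-wide error background common to most sites was argued against, since 0.212% of 472 adenosine sites outside the Q tRNAs were as low as A36 and 0.872% of 917 cytidine sites were as low as C32. Both sites were chosen because they passed among the 56 loop sites, and these shares do not allow for that choice. Reads of near-identical tRNA-Asn references with T at position 32 were argued against as the only source at C32, since C32A and C32G together had a log2 ratio of -1.25 without overlap, and references with A or G there were not tested. An effect of Q on reading of neighbouring bases may contribute and stays open. After background removal, 14.3% of 56 loop sites in Q tRNAs were lower by at least 1 (log2). In G34 tRNAs without Q it was 9.52% of 63, a gap of 4.76 percentage points from few sites. The 56 sites include A36 and C32 themselves and G34. The gap is therefore not independent of the pattern and does not measure neighbouring bases alone. For deletion the shares of loop sites lower by at least 1 were 25.0% and 9.52%, with 3 and 0 sites past the threshold after that removal.

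Deletion at G34 was lower in Q_plus in most Q families. For mitochondrial tRNAs a library-wide background could account for it, since relative to G34 tRNAs without Q the difference was 0.14 (log2). This stays open, since the difference was -0.14 without Q_plus replicate 1 and 0.42 without Q_plus replicate 3. It also rests on 3 families without Q, as mt-tRNA-Ile had libraries with no deleted reads and was left out. Their log2 ratios were -2.29 for mt-tRNA-Phe, -0.59 for mt-tRNA-Ser-GCT and -0.40 for mt-tRNA-Cys. Those of the Q families were -1.40 for mt-tRNA-Tyr, -1.15 for mt-tRNA-His, -1.03 for mt-tRNA-Asn and -0.63 for mt-tRNA-Asp. For cytosolic tRNAs the background and Q in place of guanosine cannot be told apart, since the relative difference of -0.60 had an exact permutation p of 0.2 and 3 of 4 cytosolic families, all but tRNA-Asn, were lower than every G34 family without Q of the cytosol. That difference stayed negative in every leave-out, from -0.42 without Q_plus replicate 1 to -0.77 without Q_plus replicate 3, with overlap between the groups in most.

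Q_plus replicate 1 stood apart from the other libraries by low guanosine mutation and high rRNA. Outside the Q tRNAs it was also lowest at every base for deletion, at -0.44 to -1.03 (log2, relative to the mean of the libraries). For stops it was lowest too, at -0.24 to -0.91. Q_minus replicate 3 was highest at every base, at 0.35 to 0.66 for deletion and 0.37 to 0.71 for stops. In guanosine mutation the other Q_plus libraries, given the same supplement, were at 0.14 and -0.02 (log2), against 0.04 to 0.70 in Q_minus. The gap of 1.00 to the nearest other Q_plus library is how this library was singled out, so it cannot decide on a part of queuine. The low mutation was also present over tRNA references alone, at -0.98. This cannot decide on a part of the high rRNA share. Each site had equal weight whatever its reads, and 1105 of the 1205 guanosine sites lay in tRNA. What set this library apart stays open, and may be technical.

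The 6 libraries can be split into groups of 3 in 10 ways, too few for a share under 0.05. The real split and the highest other split gave 2 and 0 calls for loop mutation, 2 and 0 for insertion, 0 and 0 for references and for mutation, deletion and stops over all sites, 0 and 1 for families and for loop deletion, 0 and 2 for loop stops, 0 and 6 for camera lists and 2 and 2 for fry's mixed test. Splits with as many calls as the real one, which is itself among them, numbered 1 for loop mutation and 1 for insertion, 2 for the mixed test and 10 of 10 for each of the others. With an estimated correlation camera called 0 lists in each of the 10 splits, so the 6 calls rest on the preset correlation.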
